A study of Homo sapiens with 9 samples.

How the data were processed

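RNA from 9 samples of the MKN45 gastric cancer line was measured on Illumina single-colour bead arrays, per the labels from total RNA made into biotin-labelled cRNA. The labels gave 3 groups of 3 arrays: mock, vector and YAP-S127A. The deposited signal table held, for 47231 probes, bead-summarised signals in intensity units on a linear scale. Its values showed no background subtraction, and it was used without detection p-values or control probes. The deposited series matrix held values on a log2 scale, quantile normalized between the arrays: every array had a median of 6.92, a lowest value of 6.34 and a highest of 15.0. Each of its columns had the rank order of the signal column of the same sample (rank correlation across probes of 1, and at most 0.893 with any other array). BeadStudio is the software named by the authors, and its version and settings are not given in the sources used here.

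The comparisons, tests, gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined, apart from 1 alternative named below. Some tests of explanations were chosen only after the results were seen, as each closing part says. The main analysis began from the signal table. Signals were background-corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, put on the log2 scale and quantile normalized. This was the form planned for a table without detection p-values. The offset, and any background left after the correction, shrink the fold changes of dim genes. Probes were kept when their mean over the 9 arrays lay above the lower quartile of all probes (6.18), which left 35423 probes. A table of probes and genes linked 30113 probes to 1 gene symbol and 8 to several, and 17110 probes had no listed gene. Current symbols were found through the gene ID for 30074 of the single-gene probes, from a table of the assembly GRCh38.p14 that was used only for names and for which genes are neighbours. Each gene was represented by its probe with the highest mean, which gave 16180 genes tested.

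All 9 arrays entered 1 limma fit with a mean per group, with 6 residual and 16.4 prior degrees of freedom. YAP-S127A was compared with vector and with mock, and vector with mock. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Genes called against both controls were those past this threshold in both YAP-S127A comparisons in the same direction. Standard errors are those of limma. The overlap of both comparisons was set against independent lists of the same sizes and against 50 simulations of unchanged groups that shared the YAP-S127A arrays.

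Genes were named by a rule. It took every YAP1 probe, and the 12 genes that rose most and the 12 that fell most against both controls, ranked by the smaller change, with all YAP-S127A arrays beyond all control arrays. It further took up to 8 genes each way between the controls, the 5 that rose and the 5 that fell most in each YAP-S127A comparison, the 2 to 4 members with the lowest adjusted p in each list described, and members of the YAP/TAZ-TEAD target list. A locus known only by an open reading frame name was counted and left out of the text, and 1 further gene that the rule names is not reported here. A gene named outside the rule is said to be chosen after its values were seen.

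The 34 gene lists named 757 members, of which 646 had a tested gene. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 34 lists within a comparison, and again with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. The direction given for a list is that of camera.

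Quantile normalization, the fit and the calls were tested on simulated log2 values of these 16180 genes, with 200 changed genes in each of 5 simulations. Background correction, the filter and the choice of probe were not simulated, so the compression of dim genes is left out. Noise was normal and independent between genes, with spreads drawn from the prior of the limma fit. The share of false calls therefore follows from that model. For YAP-S127A against vector 80.6% of 1.5-fold and 99.1% of 2-fold changes were recovered, with 4.32% of calls false. Against mock the values were 77.9%, 99.4% and 4.15%, and against both controls 67.4%, 98.8% and 0.338%. A shifted list of 25 genes was recovered, and 0 of 20 unshifted lists were called. As the simulated genes varied independently, this does not test list calls where genes vary together.

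The alternatives were log2 signals without background correction, scaling to equal medians, cyclic loess, the deposited log2 values, no filter on dim probes, every probe tested, the mean of the probes of a gene, only the arrays of the groups compared, moderation with trend and robust settings, array weights, replicate number as a block, thresholds of 0.01 and of 1.5-fold, and leaving out each array in turn. A filter at the median of all probes was chosen after seeing the data. The labels give no day, slide or batch that could be tested. Counts of called genes were compared with those from other splits of the arrays. Neighbouring genes were tested by shuffling calls among genes of like expression, 10000 times.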

Results

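Gene expression was measured in MKN45, an established human gastric cancer cell line, on 9 single-colour bead arrays, each hybridised with the RNA of 1 sample. The samples formed 3 groups of 3 arrays. Mock cells and cells with the empty vector served as controls, and the other group carried YAP-S127A, a form of the transcriptional coactivator YAP1 in which a serine that Hippo pathway kinases phosphorylate is replaced by alanine. The median probe signal lay between 107 and 136 intensity units on the 9 arrays and the lowest probe between 70.6 and 89.2, so that many probes sat close to the background. The number of arrays limits the precision of every value. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Across the 16180 genes tested, the first principal component held 33.4% of the variance and set the YAP-S127A arrays (scores of 14.4 to 16.8) apart from the 6 control arrays (scores of −15.9 to −4.07). Mock array 1 stood apart from the other arrays: the other controls scored from −9.24 to −4.07, and on the second component (15.3% of the variance) it scored 17.9 where the rest ran from −9.94 to 3.15.

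The arrays carried a single probe for YAP1 (ILMN_1709479), and its level did not differ detectably between the groups. Its mean normalized log2 intensity was 6.08 ± 0.09 in mock (SD, n = 3), 6.04 ± 0.09 in vector and 6.12 ± 0.06 in YAP-S127A arrays. The YAP-S127A arrays differed from vector by 0.08 ± 0.11 (SE) and from mock by 0.04 ± 0.11 on the log2 scale. The probe stood at the 12.3 percentile of all probes by mean level and failed the filter on dim probes. Whether it matches the expressed sequence is not known here, so this level does not check the labels.

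The first question was which transcripts differed in YAP-S127A cells from both controls, since the pair of controls separates the expressed protein from the delivery of a vector. CCN1, a secreted matricellular protein and an established YAP target, rose by 2.34 ± 0.11 (log2, SE) against vector and 2.65 ± 0.11 against mock, n = 3 arrays per group (limma, adjusted p = 1.04e-12 and 1.43e-13). Its control means lay close to the filter on dim probes (6.18), so these changes may be compressed, as may those of other genes with dim controls. The caveolar coat genes CAVIN1 (2.36 and 2.14) and CAV1 (1.89 and 1.78) rose as well. So did PLAU, which encodes the urokinase plasminogen activator (2.08 and 2.12), and SLC2A3, which encodes a glucose transporter (2.66 ± 0.18 and 2.00 ± 0.18). ZBED2, which encodes a zinc finger protein, rose to a mean log2 intensity of 8.05 from 5.77 in vector and 5.91 in mock arrays, which lie under the filter on dim probes (6.18), so no exact change is given. Other genes that rose were TNNC1, the troponin C of slow and cardiac muscle (2.25 and 2.12), and VGLL1, a cofactor of TEAD transcription factors (1.76 and 1.89). Rises were also seen in the secreted serine protease KLK6 (1.63 and 1.55), CCDC9B (2.83-fold and 3.08-fold) and AJUBA, a LIM-domain scaffold that binds LATS kinases (1.69 and 1.47). For KLK6 and AJUBA these values come from the brightest probe, and the dimmer probes showed no rise: 1 further KLK6 probe differed by −0.01 from vector, and the further AJUBA probes by 0.08 and 0.09. CAV1 had a further probe that rose by 2.32 against vector.

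REG4, a secreted lectin of the regenerating family, fell by 1.17 ± 0.11 (log2, SE) against vector and by 1.07 ± 0.11 against mock (limma, adjusted p = 3.22e-07 and 1.23e-06), from a mean log2 intensity of 11.48 in vector to 10.30 in YAP-S127A arrays. ANXA10, an annexin of gastric epithelium, changed by −0.90 and −0.999, CLDN18, the tight-junction claudin of the stomach, by −0.86 and −0.91, LGALS4, a galectin of the gut lining, by −0.85 and −0.82, and FCGBP, a mucus protein, by −1.04 and −0.82. The cornified envelope precursor SPRR1B fell by 1.02 against vector and changed by −0.94 against mock. The endocytic adaptor REPS2 changed by −0.89 and −0.92, and all 7 of its probes were lower against vector. The other named falls were CEMIP, a hyaluronan-binding protein (−0.85 and −0.84), the alcohol dehydrogenase ADH1A (−0.81 and −0.80), the UDP-galactose transporter SLC35A2 (−0.79 and −0.80), and SH3PXD2A, a podosome scaffold (−0.87 and −0.78). Dimmer probes of SLC35A2 (−0.07, −0.10 and −0.03 against vector) and 1 of FCGBP (0.13) did not fall, and those of CLDN18 ranged from −0.33 to 0.02. With the mean of all its probes SLC35A2 was no longer called.

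In all, 384 genes were called against both controls in the same direction, 217 higher and 167 lower, and 0 were called in opposite directions. In 216 of the rises and 164 of the falls the 3 YAP-S127A arrays lay apart from all 6 control arrays. Across all genes tested, called or not, 11.3% had such separation, where chance gives 2.38%. At least 2-fold changes against both controls were 38 rises and 1 fall, that of REG4. The arrays of YAP-S127A are shared by both comparisons. Independent lists of these sizes would share 6.18 rises and 5.69 falls, and 50 simulations of unchanged groups with the shared arrays gave 0. With no gene changed, almost no gene passes the adjusted threshold in either comparison, so this 0 does not measure the effect of sharing. Each figure leaves out what the other holds, and part of the excess may come from the shared arrays. Without vector array 3 the count was 247, without YAP-S127A array 1 it was 221 and without YAP-S127A array 2 it was 214. After scaling to equal medians in place of quantile normalization, 44.4% of the calls were rises, against 56.5% here.

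**Figure D1:**
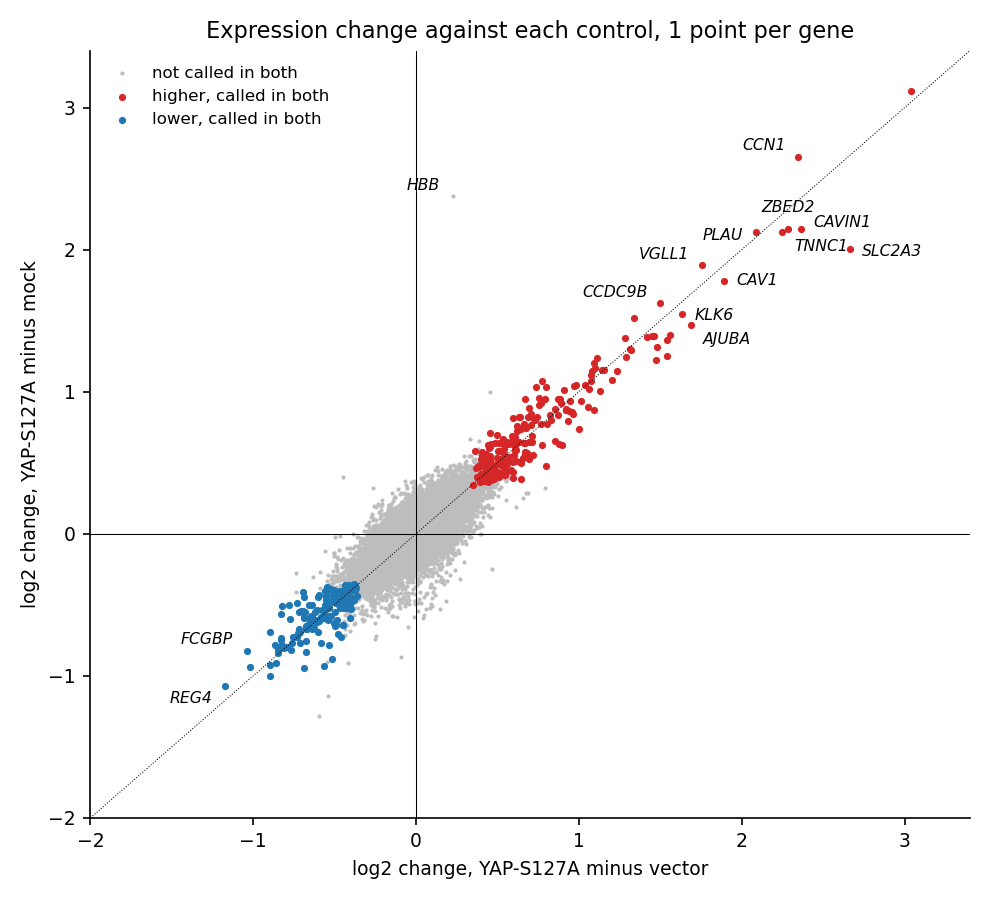
Log2 change of YAP-S127A minus vector (x axis) against YAP-S127A minus mock (y axis) for each of the 16180 genes tested, with genes called higher (red, 217) or lower (blue, 167) against both controls and the rest in grey; the dotted line marks equal change. CCN1 lies at 2.34 and 2.65, and HBB lies off the line at 0.22 and 2.38.

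**Figure D2:**
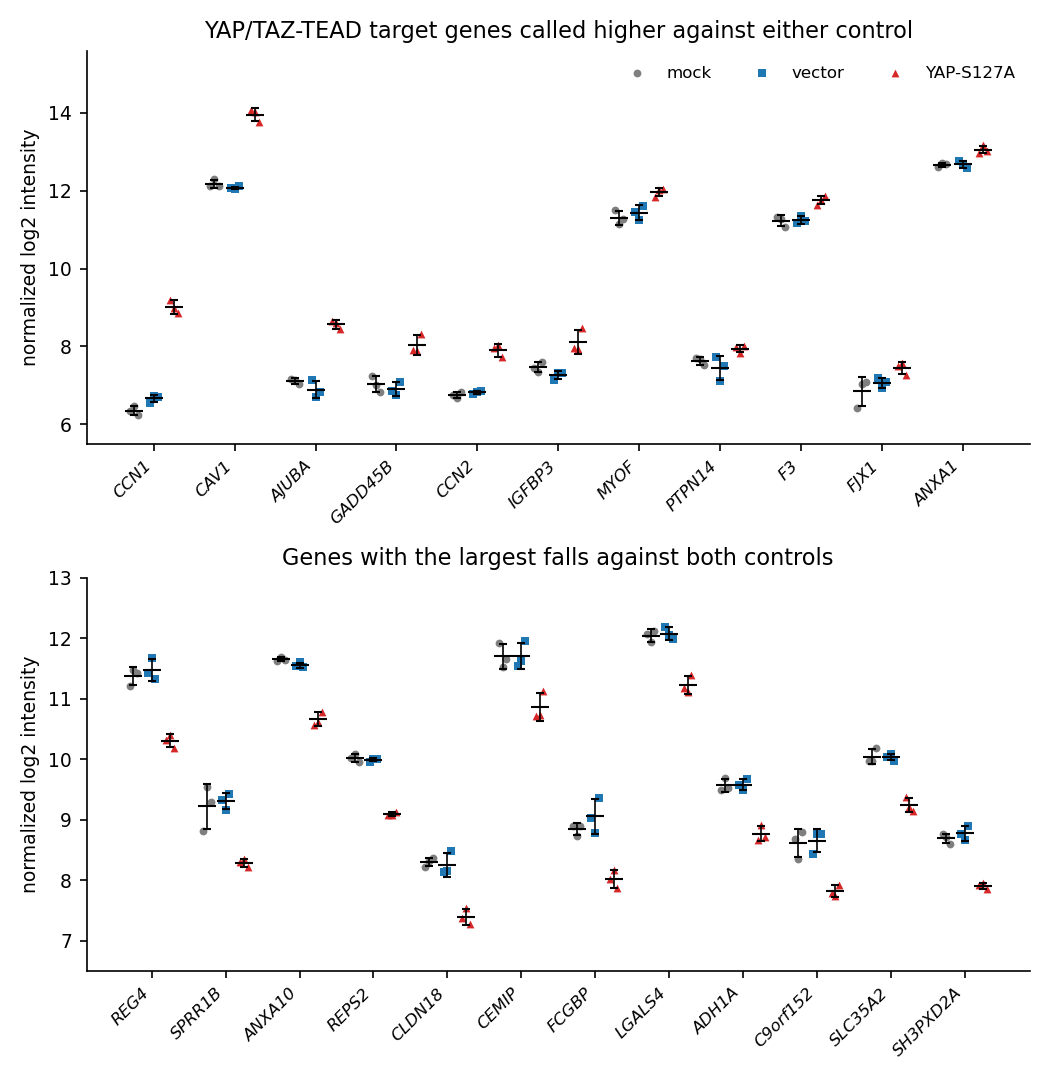
Normalized log2 intensity of each array (points; mock, vector and YAP-S127A, 3 arrays each) with the group mean and SD (bars), for YAP/TAZ-TEAD target genes called higher against either control (top) and for the 12 genes that fell most against both controls, a locus not named in the text among them (bottom). CCN1 rose from means of 6.35 and 6.66 in the controls to 9.004, and REG4 fell from 11.38 and 11.48 to 10.30.

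Against the vector control, which shares the delivery step, the targets of YAP, TAZ and TEAD moved most as a group. Of 27 measured members of this list, 10 rose, 0 fell and 17 did not pass (camera, adjusted p = 1.13e-15, and adjusted p = 0.00838 with an estimated correlation). Beside CCN1, CAV1 and AJUBA, the matricellular gene CCN2 rose by 1.08 ± 0.11 (log2, SE), the stress-response gene GADD45B by 1.13, IGFBP3, which binds insulin-like growth factors, by 0.85, MYOF, a membrane-repair ferlin, by 0.53, the phosphatase gene PTPN14 by 0.51, tissue factor F3 by 0.51 and the annexin ANXA1 by 0.38. The further CCN2 probe rose less, by 0.41. Other well-known targets did not pass: ANKRD1 differed by 0.25, AMOTL2 by 0.20, LATS2 by 0.41, AXL by 0.14 and THBS1 by −0.06. Adjusted over the list alone, 14 members rose. The calls of ANXA1, PTPN14 and MYOF ended when single arrays were left out, with adjusted p up to 0.201 (without YAP-S127A array 2), 0.195 (without vector array 2) and 0.0886 (without vector array 2). Scaling to equal medians in place of quantile normalization ended those of ANXA1 and PTPN14 too.

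Of 26 measured Hippo pathway and TEAD genes, 4 rose against vector, 0 fell and 22 did not pass (adjusted p = 0.00033, and adjusted p = 0.0418 with an estimated correlation). As defined, this list shares LATS2, AMOTL1, AMOTL2 and PTPN14 with the target list, so it is not a separate group of genes. Its mean change against vector was 0.19 and its median 0.08. VGLL1 and PTPN14 are given above, the upstream scaffold WWC1 rose by 0.71 ± 0.10 and the transcription factor TEAD4 by 0.57 ± 0.10, a call that ended with the mean of the gene's probes. Adjusted over the list alone, 7 rose and 1 fell. NF-kB and chemokine genes were higher, with 4 of 15 members risen and 0 fallen (adjusted p = 6.68e-05, and adjusted p = 0.0418 with an estimated correlation, or 5 risen adjusted over the list alone). The neutrophil chemokines CXCL8 and CXCL1 rose by 1.23 ± 0.14 and 1.20 ± 0.15. CXCL16 (0.41) and the NF-kB inhibitor TNFAIP3 (0.44) were called too, and their calls ended without any 1 of 6 arrays, with adjusted p up to 0.171 (without YAP-S127A array 1) and 0.112 (without vector array 2), as they did after scaling to equal medians.

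Gastric and intestinal differentiation genes were lower against vector, with 4 of 22 members fallen, 0 risen and 18 not passing (adjusted p = 0.00316, but adjusted p = 0.129 with an estimated correlation). Besides REG4 and LGALS4, the trefoil peptide gene TFF1 changed by −0.90 ± 0.13 and the intestinal cadherin CDH17 by −0.44 ± 0.11. The call of CDH17 ended without vector array 3 (adjusted p = 0.143), vector array 2, or YAP-S127A arrays 1 or 2. Adjusted over the list alone, 7 members fell and 1 rose.

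Each of the following list calls against vector was lost with an estimated correlation. DNA replication genes were higher, with 3 of 28 risen, among them MCM5, a subunit of the replicative helicase, by 0.55 (adjusted p = 0.00033, and adjusted p = 0.234 with an estimated correlation). Without vector array 2 the adjusted p of MCM5 was 0.0687. The 30 mitosis genes were higher as a set (adjusted p = 0.0127, and adjusted p = 0.234 with an estimated correlation) while 0 members passed alone, and without vector array 3 the adjusted p of the list was 0.0512. Ribosome biogenesis genes were higher (adjusted p = 0.00316, and adjusted p = 0.523 with an estimated correlation, or 0.0849 without YAP-S127A array 2), with 1 of 23, the spermidine synthase gene SRM, risen by 0.80. Actin and SRF target genes were higher (adjusted p = 0.0245, and adjusted p = 0.178 with an estimated correlation), with 2 of 20 risen, the tropomyosin gene TPM1 by 1.09 ± 0.10 and the calponin gene CNN3 by 0.48. This list's adjusted p was 0.0512 without vector array 3, which also ended the call of CNN3 (0.0565), and 0.0586 without YAP-S127A array 1. NRF2 and metallothionein genes were lower, with 2 of 16 fallen, the aldo-keto reductase AKR1B10 by 0.69 and the glutathione synthesis gene GCLC by 0.40, and 1, the heme oxygenase HMOX1, risen by 0.64 (adjusted p = 0.0283, and adjusted p = 0.442 with an estimated correlation). That list's call ended without vector array 1 (adjusted p = 0.1), vector array 3, or YAP-S127A arrays 1 or 2. The calls of GCLC and HMOX1 also ended without single arrays (adjusted p up to 0.158 without YAP-S127A array 1, and 0.0537 without vector array 3). After scaling to equal medians MCM5, CNN3 and GCLC were no longer called. Adjusted over the list alone, the rises and falls were 5 and 0 for DNA replication, 0 and 0 for mitosis, 1 and 0 for ribosome biogenesis, 2 and 0 for actin, and 1 and 5 for the NRF2 list.

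In total 559 genes were called against vector by limma, 284 higher and 275 lower, of which 41 rose and 3 fell at least 2-fold. After scaling to equal medians 38.5% of the calls were rises, against 50.8% here. The count was 337 without vector array 2, 309 without vector array 3, 333 without YAP-S127A array 1 and 291 without YAP-S127A array 2.

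Against the mock control, the same question was asked without a vector in the control cells. The YAP/TAZ-TEAD target list again showed 10 rises and 0 falls among 27 members (adjusted p = 9.91e-15, and adjusted p = 0.00995 with an estimated correlation, or 12 risen adjusted over the list alone), and 9 of the risen members were called against both controls. FJX1, which encodes a Golgi protein linked to Fat and Dachsous signalling, rose by 0.60 ± 0.14 here and differed by 0.38 from vector, with a rise of 0.39 (adjusted p = 0.0935) against mock without mock array 1 and a call that also ended after scaling to equal medians, while PTPN14 differed by 0.32 from mock and did not pass. Hippo pathway and TEAD genes (3 of 26 risen, adjusted p = 0.00201, and adjusted p = 0.0698 with an estimated correlation) and NF-kB and chemokine genes (3 of 15 risen, adjusted p = 0.000277, and adjusted p = 0.0698 with an estimated correlation) were higher, with VGLL1 at 1.89, WWC1 at 0.84, CXCL8 at 1.15 and CXCL1 at 1.08. Gastric and intestinal differentiation genes were lower, with the same 4 members fallen, and 1, the fatty acid binding protein gene FABP1, chosen after its values were seen, risen by 0.40 (list adjusted p = 0.0148, and adjusted p = 0.144 with an estimated correlation). That list's call ended without mock array 3 (adjusted p = 0.0954) and without YAP-S127A array 1 (0.0511).

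Lists for DNA replication, ribosome biogenesis, mitosis, actin and heat shock were higher against mock. DNA replication genes had 6 of 28 risen (adjusted p = 1.65e-07, and adjusted p = 0.0926 with an estimated correlation), such as UHRF1, a maintenance factor of DNA methylation, at 0.43, and CDC45, a helicase cofactor, at 0.48. Without YAP-S127A array 2 the adjusted p of UHRF1 was 0.0935, and without YAP-S127A array 1 that of CDC45 was 0.0746. Ribosome biogenesis genes had 6 of 23 risen (adjusted p = 1.32e-05, and adjusted p = 0.254 with an estimated correlation), led by SRM at 0.77 ± 0.14. The list averaged 0.14 and 0.22 above its mean over all arrays on YAP-S127A arrays 1 and 2, but −0.01 on YAP-S127A array 3, within the range of the vector arrays (−0.04 to 0.01). Mitosis genes were higher with 0 of 30 called (adjusted p = 0.0326, and adjusted p = 0.254 with an estimated correlation), and the list's call ended without mock arrays 1 or 3 or YAP-S127A arrays 1 or 2, with adjusted p up to 0.162 (without mock array 3). Actin and SRF targets had 3 of 20 risen (adjusted p = 0.0013, and adjusted p = 0.0698 with an estimated correlation), with TPM1 at 1.20 ± 0.10. Heat shock genes were higher (adjusted p = 0.019, and adjusted p = 0.254 with an estimated correlation) with 1 of 16, the co-chaperone DNAJB1, risen by 0.47. The heat shock list averaged 0.10 on both YAP-S127A arrays 1 and 2 but 0.00 on array 3. The call of this list ended without mock array 3 (adjusted p = 0.137) or YAP-S127A arrays 1 or 2, and that of DNAJB1 without YAP-S127A array 2 (0.0858) among others. Scaling to equal medians ended the calls of the mitosis and heat shock lists and of UHRF1, CDC45 and DNAJB1.

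Lists for hypoxia and glycolysis, NRF2 and metallothionein genes, and cholesterol synthesis were lower against mock. The vector arrays showed part of each shift. In that order, the mean changes were −0.20, −0.30 and −0.16 against mock, and −0.14, −0.15 and −0.11 for vector against mock. Against vector they were −0.07, −0.16 and −0.05, where only the NRF2 list was called. Of 29 hypoxia and glycolysis genes 7 fell, 1 rose and 21 did not pass (adjusted p = 8.53e-05, and adjusted p = 0.254 with an estimated correlation). The aldolase ALDOC changed by −1.29 ± 0.17 and the glycolysis regulator PFKFB4 by −0.78 ± 0.15, while SLC2A3 rose by 2.00 as given above. Of 16 NRF2 and metallothionein genes 5 fell and 0 rose (adjusted p = 9.36e-05, and adjusted p = 0.121 with an estimated correlation), with the metallothionein MT2A at −1.14 ± 0.20 and MT1E at −0.87 ± 0.17. Both metallothionein calls ended when the moderation allowed for a trend and for unusual spreads. Cholesterol synthesis genes were lower (adjusted p = 0.00474, and adjusted p = 0.105 with an estimated correlation), with 2 of 19 fallen, HMGCS1, an early enzyme of the pathway, by 0.58 and its regulator INSIG1 by 0.48. Without YAP-S127A array 1 the adjusted p of HMGCS1 was 0.062, and without YAP-S127A array 2 that of INSIG1 was 0.0832; its call also ended with the mean of its probes. The arrays within a group were uneven in these lists. The hypoxia genes averaged 0.24 above their mean over all arrays on mock array 1 and 0.11 on mock array 3, but −0.01 on mock array 2, and 0.05 on YAP-S127A array 3 against −0.16 on both other YAP-S127A arrays. The NRF2 list averaged 0.19, 0.06 and 0.20 on mock arrays 1, 2 and 3, and −0.20, −0.23 and −0.03 on YAP-S127A arrays 1, 2 and 3. The cholesterol list averaged 0.14, 0.05 and 0.09 on the mock arrays and −0.12, −0.08 and −0.01 on the YAP-S127A arrays. In all 3 lists YAP-S127A array 3 was the nearest of its group to the mock arrays. Adjusted over the list alone, the rises and falls against mock were 1 and 11 for hypoxia, 2 and 8 for NRF2, 0 and 3 for cholesterol, 8 and 0 for DNA replication, 10 and 0 for ribosome biogenesis, 0 and 0 for mitosis, 4 and 0 for actin, 1 and 0 for heat shock, 4 and 0 for Hippo, 5 and 0 for NF-kB, and 1 and 6 for the gastric list.

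Beside genes given above, the largest falls against mock included DEPTOR, an inhibitor of mTOR kinase (−0.95 ± 0.14 against mock and −0.69 ± 0.14 against vector). The vector call of DEPTOR ended without vector array 3 or YAP-S127A array 2 (adjusted p of 0.0518 in both cases). In total 687 genes were called against mock by limma, 352 higher and 335 lower, of which 45 rose and 3 fell at least 2-fold. After scaling to equal medians 31.3% of the calls were rises, against 51.2% here. The count was 381 without mock array 1, 341 without YAP-S127A array 1 and 325 without YAP-S127A array 2.

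**Figure D3:**
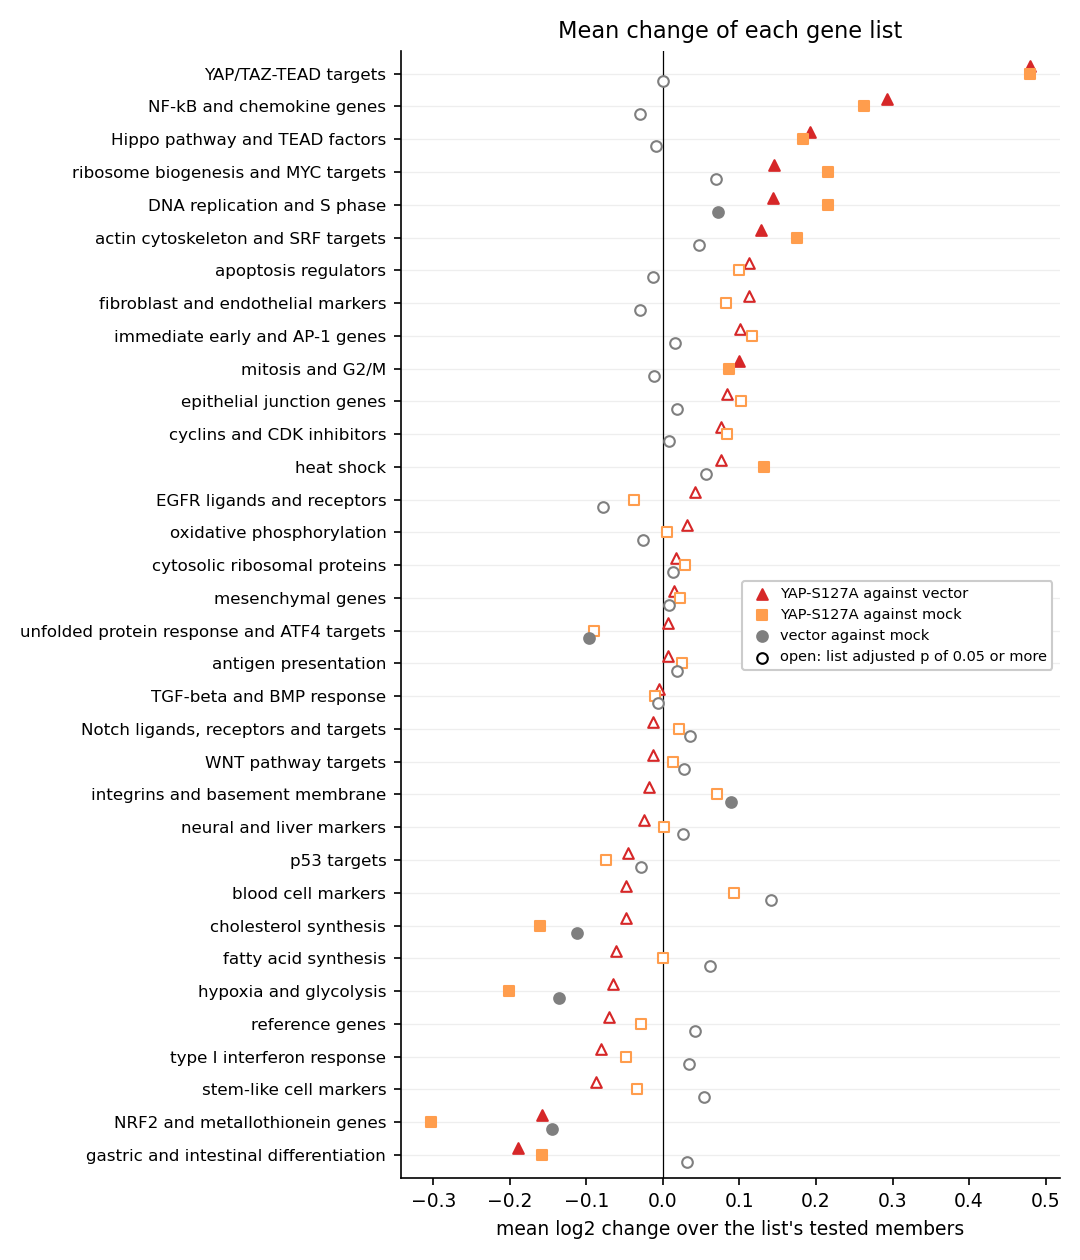
Mean log2 change over the tested members of each of the 34 gene lists (x axis) in the 3 comparisons, with filled symbols where the list passed (camera, adjusted p under 0.05) and open symbols elsewhere. The YAP/TAZ-TEAD targets lie farthest right at 0.48 in both YAP-S127A comparisons and at 0.00 between the controls.

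The controls were compared with each other to measure what the vector alone changed. By limma 2 genes were called, both higher with the vector. Of the 16180 genes tested, 911 had an unadjusted p under 0.05. With no gene changed, a share of about 0.05 of all genes would reach that level, so the 911 do not count effects of the vector. HBB, which encodes beta-globin (probe ILMN_2100437), rose by 2.15 ± 0.12 (log2, SE, adjusted p = 2.35e-10), from 6.43 ± 0.11 (SD, n = 3) in mock to 8.58 ± 0.29 in vector arrays. It stood at 8.80 ± 0.05 in YAP-S127A arrays, 2.38 above mock, and its difference of 0.22 from vector did not pass (adjusted p = 0.402). The mock levels of HBB lay within the range of the HBA2 probes over all arrays (6.15 to 6.69), so its changes from mock may be compressed. TAOK1, a kinase upstream of the Hippo cascade, rose by 0.85 ± 0.13 (adjusted p = 0.0154) and was at an intermediate level of 8.404 in YAP-S127A arrays, between 8.004 in mock and 8.85 in vector. The TAOK1 call ended without mock array 2 (adjusted p = 0.212), vector array 2 (0.136), vector array 3 (0.378) or YAP-S127A array 3 (0.0545), and also with the deposited normalized values, with the mean of its probes, or with only the arrays of the controls in the fit. Without mock array 3, 54 genes were called, 46 of them lower.

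Of the 34 lists 6 were called between the controls, and each call was lost with an estimated correlation. In the comparison of YAP-S127A with mock 4 of these were called too: hypoxia and glycolysis, NRF2, cholesterol synthesis and DNA replication. Integrin and basement membrane genes (adjusted p = 0.0364, and adjusted p = 0.666 with an estimated correlation) and DNA replication genes (the same adjusted p in both tests) were higher with the vector, with 0 members called. Cholesterol synthesis (adjusted p = 0.0118, and adjusted p = 0.513 with an estimated correlation), unfolded protein response (adjusted p = 0.0364, and adjusted p = 0.746 with an estimated correlation), hypoxia and glycolysis (adjusted p = 0.00236, and adjusted p = 0.666 with an estimated correlation) and NRF2 genes (adjusted p = 0.0356, and adjusted p = 0.666 with an estimated correlation) were lower, again with 0 members called. The hypoxia call ended without mock array 1 (adjusted p = 0.156), and that of the unfolded protein response without mock array 1 (0.575), on which its members averaged 0.18 above their mean. Without mock array 3 the other calls ended at adjusted p of 0.492 (integrins), 0.244 (DNA replication), 0.109 (cholesterol) and 0.295 (NRF2). Scaling to equal medians ended the calls of the integrin and DNA replication lists. Adjusted over the list alone, 1 integrin gene rose and 2 genes each of the cholesterol, hypoxia and NRF2 lists fell, and 0 genes of the DNA replication and unfolded protein response lists passed. The YAP/TAZ-TEAD targets had 0 members called between the controls (adjusted p = 0.879), where their median was −0.01 and their mean 0.00.

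**Figure D4:**
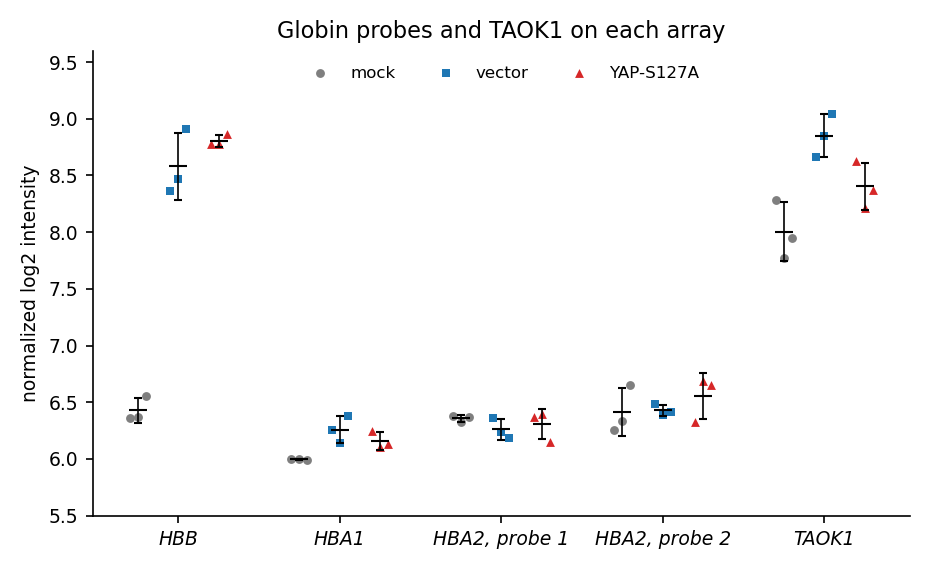
Normalized log2 intensity of each array (points; 3 arrays per group) with the group mean and SD (bars) for the HBB, HBA1, HBA2 and TAOK1 probes. HBB lies at 6.36 to 6.56 on the mock arrays and at 8.36 to 8.91 on the vector and YAP-S127A arrays, whereas the HBA1 and HBA2 probes reach at most 6.69 on any array.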

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

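Of the tests in this part, that of a vector-carried HBB sequence was chosen only after the result was seen.

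HBB is listed here because the effect of YAP-S127A on it depended on the control: the change against mock exceeded that against vector by 2.15 on the log2 scale, which is the tested difference between the controls. The probe lay at 6.36 to 6.56 on the mock arrays, 8.36 to 8.91 on the vector arrays and 8.77 to 8.86 on the YAP-S127A arrays. RNA from red blood cells would bring alpha-globin as well, and the highest upper 95% bound of the change over the HBA1 and HBA2 probes was 0.477, below the bound of 1.076 derived from the HBB change. That bound was of the HBA1 probe, which was itself higher with the vector, by 0.26 (95% interval 0.05 to 0.48, limma, unadjusted p = 0.0188). The HBA2 probes changed by 0.01 and −0.10. On each mock array HBA1 lay under the filter on dim probes (6.18), so its change may be compressed, as may that of HBB. A small rise of alpha-globin is therefore not excluded. A single deviating array is argued against by the lowest HBB change without any 1 array, 1.98. An HBB sequence carried by the vector and expression of the cells' own HBB after delivery cannot be told apart with a single HBB probe. Both would give the gap of 1.80 between the lowest array with a vector and the highest mock array, the difference of 0.22 ± 0.12 (SE) between vector and YAP-S127A arrays, and the highest upper bound of 0.478 over 16 other globin and red cell probes.

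TAOK1 met the same criterion, with effects of YAP-S127A against mock and against vector that differed by 0.85 (log2, the difference between the controls), although the call was lost on leaving out some arrays, as given with the comparison of the controls. In 1 of the 10 splits of the 6 control arrays into groups of 3, the real one, 2 genes were called, and the highest count of the other splits was 0. These splits are too few for a share under 0.05. With vector and YAP-S127A arrays the real split gave 559 genes and the highest other 0, in 1 of 10 splits, and with mock and YAP-S127A arrays 687 and 0, in 1 of 10, where the splits are again too few. In all these comparisons every other split mixed the groups compared. That moves any difference between them into the spread within groups, so few calls could arise there.

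A signal also appeared in probes without a listed gene, which the comparisons of genes did not use. Of 12706 such probes past the filter, 56 were called higher and 26 lower against both controls. The probe ILMN_2387385 rose by 2.74 against vector and 2.63 against mock, and ILMN_1661628 by 2.33 and 2.34, while ILMN_1748303 changed by −0.99 and −0.78 and ILMN_1874323 by −0.92 and −0.84. These 4 probes were chosen after their values were seen. A test of the gap between 1 sample and the rest of its group was not run, as groups of 3 arrays are too small for it.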

How the results depend on the processing

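The filter at the median of all probes was the test here chosen only after the results were seen. Across the alternatives, thresholds and omitted arrays, 181 values of named genes gave 3981 refits, of which 3501 kept direction and call, 480 kept the direction but not the threshold, and 0 reversed. At least 1 setting cost 85 of the values the threshold. For 27 list calls, 305 of 378 refits kept direction and call, 73 kept the direction only, and 0 reversed.

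The count against vector was 366 after scaling to equal medians, 271 at a threshold of 0.01 and 195 with 1.5-fold required. The count against mock was 291 and 211 at those thresholds, and that against both controls 201 and 151. Stricter thresholds lower a count by construction; for the scaling the cause was not tested. With 1 array left out the counts ran from 291 to 738 against vector, 325 to 820 against mock and 214 to 370 against both controls. Between the controls the count was 1 with the deposited log2 values, with the mean of probes, with only the arrays compared and at the threshold of 0.01, and it ran from 1 to 54 with 1 array left out. The cause was not tested.

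With an estimated correlation in camera 3 lists were called against vector, 1 against mock and 0 between the controls. By fry, which does not compare a list with other genes, the numbers were 6, 14 and 0. The number of lists called between the controls ran from 1 to 7 with 1 array left out. The cause was not tested.

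The replicate numbers did not pair the samples: correlations of gene deviations between arrays of the same number ran from −0.146 to 0.10 over 9 pairs. With replicate number as a block the counts were 558 against vector, 648 against mock, 2 between the controls and 369 against both. The other alternatives kept each total count of genes within 1.5 times the main count, and the YAP1 difference kept within the spread of its arrays. Counts of rises moved more. After scaling to equal medians 114 genes rose and 143 fell against both controls, where the main setting gave 217 and 167. Against mock that scaling called 470 genes, 31.3% of them rises.

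Normexp without detection p is the main setting itself, and a filter on detection p and a slide block were not run, as no such values or labels were used. Signal over background limits the values: the lowest probes read 70.6 to 89.2 and the array medians 107 to 136, so falls of dim genes are compressed.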

Other observations

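The tests of the signal floor, of 2-fold changes under other scalings, of the YAP1 probe and of gene families among neighbours were chosen only after the result was seen.

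Of the 34 lists, 22 were called in neither YAP-S127A comparison, although single members changed in both directions. Among 21 epithelial junction genes the keratin genes KRT18 (1.54 against vector and 1.25 against mock, log2) and KRT8 (0.85 and 0.88) and the claudin gene CLDN1 (0.74 and 0.82) rose, while the desmosomal gene DSP changed by −0.51 against vector and CLDN3 by −0.50 against mock (camera, adjusted p = 0.567, where median and mean differed in sign, and 0.301). The DSP call ended with the mean of its probes, and the CLDN3 call without YAP-S127A array 2 (adjusted p = 0.0801). Among 20 immediate early and AP-1 genes the phosphatase gene DUSP5 rose by 0.94 against both controls and the AP-1 subunit FOSL1 by 0.77 and 0.92 (adjusted p = 0.297, with signs that differed, and 0.192). Of 14 stem-like cell markers the aldehyde dehydrogenase ALDH1A3 rose by 1.15 ± 0.11 against both controls, and SOX2 changed by −0.47 against vector (adjusted p = 0.0736 and 0.367), a call lost with the mean of its probes. CD44 and KLF4 were called lower against vector too, and these calls ended without single arrays (limma, adjusted p up to 0.137 and 0.10). Adjusted over the list alone, 1 marker rose and 5 fell against vector, and 1 rose and 4 fell against mock. Of 15 cyclins and CDK inhibitors the kinase CDK6 rose by 0.63 and 0.65 (adjusted p = 0.327 and 0.324, signs differing in the latter). Of 17 apoptosis regulators BCL2L1, an inhibitor of apoptosis, rose by 0.48 and 0.64 (adjusted p = 0.0736 and 0.16). Its vector call ended after scaling to equal medians. The pro-apoptotic gene BIK was also called higher against both controls, and the pro-apoptotic gene PMAIP1 against vector. The calls of BIK and PMAIP1 ended when single arrays were left out, with a limma adjusted p up to 0.213 (BIK against mock, without mock array 1).

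In signalling lists the Notch ligand DLL3 rose by 0.56 and 0.64 and the Notch target HEY1 changed by −0.91 against mock and by −0.42, not called, against vector (17 genes, adjusted p = 0.93, signs differing, and 0.62). In the same list HES4 was called higher against both controls, and LFNG and NOTCH3 lower against vector. The calls of HES4, LFNG and NOTCH3 ended when single arrays were left out. In the TGF-beta and BMP list the BMP target ID2 changed by −0.64 and −0.67 and the pseudoreceptor BAMBI by 0.56 and 0.49 (17 genes, adjusted p = 0.958 and 0.977), and the mock call of BAMBI ended without YAP-S127A array 2 (0.0789). The receptor ERBB3 changed by −0.42 and −0.50 among 9 EGFR ligands and receptors (adjusted p = 0.586 and 0.856), and its calls ended without vector array 3 (0.187, against vector) and without YAP-S127A array 1 (0.0527, against mock). In the interferon list ISG20 changed by −0.52 and −0.88 (27 genes, adjusted p = 0.121 and 0.505), with adjusted p = 0.154 against vector without vector array 3. The lysozyme gene LYZ changed by −0.77 and −0.60 among 15 blood cell markers (adjusted p = 0.586, and 0.977 with signs differing); its mock call ended with the mean of its probes. The remaining lists gave adjusted p, against vector and mock, of 0.875 and 0.977 (WNT targets), 0.779 and 0.846 (mesenchymal genes, signs differing in both), 0.586 and 0.393 (p53 targets), 0.958 and 0.856 (antigen presentation), 0.714, signs differing, and 0.58 (ribosomal proteins), 0.494 and 0.995, signs differing (fatty acid synthesis), and 0.943, signs differing, and 0.217 (unfolded protein response). They gave 0.586 and 0.977 (oxidative phosphorylation), 0.779 and 0.333 (integrins), 0.0987 and 0.301 (fibroblast and endothelial markers), 0.779, and 0.995 with signs differing (neural and liver markers), and 0.448 and 0.846 (reference genes). Within these remaining lists MYC, a WNT target, was called higher and SCD, of fatty acid synthesis, lower against both controls. The vector call of MYC and both calls of SCD ended when single arrays were left out. Against vector alone cholesterol synthesis (0.494), heat shock (0.209) and hypoxia (0.0525) were not called. Between the controls the 28 lists not called had adjusted p from 0.0622 to 0.879.

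The YAP1 probe stayed at background while YAP target genes rose. A swap of single arrays between YAP-S127A and the controls is argued against by the mean of the 27 targets. In it the lowest YAP-S127A array exceeded the highest control array by 0.409, where the 6 control arrays spanned 0.0975. The rise of these targets is part of the pattern itself, so the gap is no independent check of the group labels. A probe outside the expressed sequence may explain why the YAP1 probe did not rise in YAP-S127A arrays, though not by itself its low level in mock arrays (6.08). A probe at the 12.3 percentile in all groups could equally be one that does not respond. These cannot be told apart here.

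Among genes called against both controls the median rise was 0.603 and the median fall 0.529 (absolute log2), and at least 2-fold changes were 38 rises and 1 fall. For the medians a floor of the signal scale may account for the gap, since among genes with a control mean of at least 9 the difference of rises minus falls was −0.032 (67 rises, 99 falls, permutation p = 0.364); the lowest ratio of rise to fall over other scalings and background treatments, 1.11, had a bootstrap interval of 1.03 to 1.25 and left normalization open. For the 2-fold changes both are argued against as the whole cause: 8 of those bright genes rose and 1 fell at least 2-fold (Fisher's exact p = 0.00325, two-sided), and the other scalings and background treatments gave from 24 to 38 rises and 1 or 2 falls of at least 2-fold. The permutation, bootstrap and Fisher tests took genes as independent units, although all were measured on the same arrays and may change together. Their results measure the spread over genes and not that between samples. A share of cells without the expressed protein cannot be told apart, as REG4 kept 45.9% of its control level. A biological difference between rises and falls stays open and was not tested further.

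The hypothesis that genes changed together with their neighbours was tested on 16163 placed genes. Consecutive genes both called higher formed 11 pairs, against a mean of 3.07 after shuffling (permutation p = 0.0003), such as KRT8 with KRT18, CAV1 with CAV2 and KLK5 with KLK6, and both called lower 7 pairs, against 1.86 (permutation p = 0.0025), such as ADH1A with ADH1C. CAV2, KLK5 and ADH1C were chosen after their values were seen. Families of related genes, or probes that bind more than 1 family member, may contribute. Pairs with unlike symbols numbered 6 for rises (mean 2.87, permutation p = 0.069) and 5 for falls (mean 1.83, permutation p = 0.038), without adjustment of these p-values. Relatedness was judged only by the first 3 letters of the symbols. The part of gene families therefore cannot be told apart for rises or for falls.

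Other splits of all 9 arrays into 3 groups of 3 were drawn for the count called against both controls. As many as 384 genes were called in 1 of 100 splits, the real one. This shows that the YAP-S127A arrays differed from the controls as a block, but it does not exclude chance. Splits that part these arrays move their difference into the spread within groups, so few calls could arise there. The splits do not test chance differences between cultures. The highest other count was 348, in the 1 other drawn split that kept the YAP-S127A arrays together, and the 98 splits that parted them gave 0.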
